A study of Danio rerio with 14 samples.

How the data were processed

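Stranded libraries were made per the labels from total RNA of whole larvae with removal of ribosomal RNA and sequenced as paired reads. The submitters' processing notes name FastQC, cutadapt, STAR, featureCounts and DESeq2 without versions. The genome build, the annotation and the strand setting are not given in the sources used here. For each compound the authors deposited a table of signal per gene and library, in normalized counts, that is, reads per gene divided by 1 size factor per library. Whole reads were recovered from the steps of these values for 100% of the values, within a tolerance of 0.01 reads. The DMSO reads were the same in both tables, and their deposited values differed by a ratio between 1.00296 and 1.00541 because each table was normalized on its own. The authors also deposited, per compound, log2 fold changes against DMSO with their standard errors, in columns named as DESeq2 names them. A p-value and an adjusted p-value per gene stand in the same tables, as computed by the authors.

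The design was planned for 14 libraries, with 4 DMSO libraries against 5 of each compound. The tables hold columns for 12 libraries, so 4 were compared with 4, and the fifth sample of boscalid and the fifth of M510F01 were not analysed here. Groups were taken from the labels. Nothing in the labels says whether replicates are separate clutches, tanks or pools, so each library was treated as a replicate and a p measures the spread between these samples. Total reads assigned to genes ran from 12893093 to 17060350 per library. Within groups, the chi-square per gene between pairs of libraries lay between 5.43 and 41.7, so replicates are not copies of one library.

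Differences were tested with limma 3.58.1 in R 4.3.3, with the trend and robust settings, on log2 of the normalized count plus 1. Genes with a mean normalized count of at least 10 over the libraries compared were tested. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05, and intervals are 95% confidence intervals. Each compound was compared with DMSO within its own table. For the difference between M510F01 and boscalid all 12 libraries were rescaled together by median-of-ratios size factors and fitted jointly. Every adjusted p given for a gene comes from limma unless another tool is named. Reads recovered from the tables were also tested with edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

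Before the data were examined, 48 gene lists were fixed for the tissues and pathways of a larva, and the comparisons, tests, other settings to try and the rule for naming genes were set. Of 1457 list entries 1406 were matched to a gene of the tables. Lists were tested with camera at a preset correlation between genes of 0.01, and again with a correlation estimated from the data, and with fry, whose directional test asks whether the genes of a list move on balance one way. Camera compares a list with all other genes and fry does not. For each list the members past the threshold were counted over all genes tested and adjusted over the list alone.

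Genes were named by rule. Among genes past the threshold with a mean count of at least 50 and a symbol that is not a clone or locus placeholder, those with the 10 largest changes in each direction were to be named. Where fewer than 5 genes passed, the rule took the 10 genes with the smallest p under the same limits, with values and no call. Succinate dehydrogenase genes, cyp1a and cyp3a65 were always named, and for each list described the 2 to 4 members with the smallest p. Placeholder loci were looked up by gene number in the RefSeq annotation of the GRCz12tu assembly, which served for names and neighbouring genes only.

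Alternatives changed 1 choice at a time, apart from the joint fit and the term for replicate numbers combined with an estimated correlation. They covered the pseudocount, the filter, TMM and upper-quartile rescaling, limma without the robust setting, array quality weights, edgeR, DESeq2, the replicate number as a block, a joint fit and leaving out each library in turn. Added after seeing the data were the first within-group component as a covariate, leaving out libraries that stood apart, and a term for replicate numbers 1 and 2 against 3 and 4, alone and with an estimated correlation. The within-group component was the first principal component of the deviations of all 12 libraries from their group means. Correlation of the fold changes of both compounds was compared with 100 simulations of independent genes and 1000 draws that retained the covariance between genes, each with shared controls.

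The tests were tried on simulated data with 200 changed genes. For boscalid against DMSO limma called 16.4% of genes changed 1.5-fold, 85.1% of those changed 2-fold and 98.5% of those changed 4-fold, with 11 unchanged genes called. For M510F01 the shares were 23.9%, 86.6% and 100%, with 7 unchanged genes called, and for the direct comparison 32.8%, 76.1% and 98.5%, with 8. DESeq2 called 41, 40 and 39 unchanged genes in the same data. A planted list was called in each comparison and 0 of the other lists were. Each gene was drawn independently, so this does not test the preset correlation for lists whose genes vary together. When the real libraries were regrouped into other sets of 4 and 4, many lists passed with the preset correlation. The median was 19 lists for boscalid, 18.5 for M510F01 and 15.5 for the direct comparison.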

Results

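Zebrafish of the AB wild-type strain were exposed from 3 hours post fertilization (hpf) to boscalid, a fungicide that inhibits succinate dehydrogenase, or to M510F01, a metabolite of boscalid. Both were given at 0.03 µg/L, and control animals received the solvent dimethyl sulfoxide (DMSO) at 0.01%. RNA of whole larvae was taken at 96 hpf and sequenced after removal of ribosomal RNA. The tables held 4 libraries of each of the 3 groups, and the fifth sample of boscalid and the fifth of M510F01 were not analysed here. The 12 libraries held between 12893093 and 17060350 reads assigned to genes. At least 1 read in some library was found for 33541 of 36351 genes. The labels do not say whether the replicates of a group came from separate clutches or tanks, so the p-values measure the spread between these samples only. The first component of the differences between libraries of one group held 37.9% of the variance within groups. On this component the libraries numbered 1 and 2 were negative in each group and those numbered 3 and 4 were positive.

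The first comparison asked which transcripts differed between boscalid and DMSO larvae. Boscalid larvae held less RNA of cyp1b1 and cyp1a. These are cytochrome P450 family 1 genes and classic targets of the aryl hydrocarbon receptor (AhR), a ligand-activated transcription factor. Cyp1b1 (LL0000008548) was 4.90-fold lower, at 72.5 ± 10.3 normalized counts with boscalid and 359.4 ± 53.3 with DMSO (SD, n = 4 each; log2 fold change -2.29, SE 0.15, limma adjusted p = 0.00029). Cyp1a (LL0000008547) was 3.27-fold lower, at 450.2 ± 73.1 against 1503 ± 447 (log2 fold change -1.71, SE 0.19, adjusted p = 0.019). In the same family, cyp1c1 (-1.26, SE 0.18, adjusted p = 0.11) and cyp1c2 (-0.60, SE 0.12, adjusted p = 0.36) had negative estimates that did not pass. Cyp1d1 was not lower, at 0.13 (SE 0.097, adjusted p = 0.69). The largest fall past the threshold was that of FP017215.1 (LL0000010677), at -2.70 (SE 0.25, adjusted p = 0.0054) and from 127.4 ± 23.1 to 19.4 ± 6.27 normalized counts. The gene reference, matched on the gene number, lists this locus as the long non-coding RNA slincR beside sox9b, and slincR is known to be induced through AhR in zebrafish larvae. The remaining gene past the threshold, CR926130.1 (LL0000007182), fell from 922 ± 249 to 282.3 ± 48.8 (-1.69, SE 0.19, adjusted p = 0.019) and had no match in the reference. FP017215.1 and CR926130.1 lie outside the rule for named genes because of their clone names, and were named after their values were seen.

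**Figure D1:**
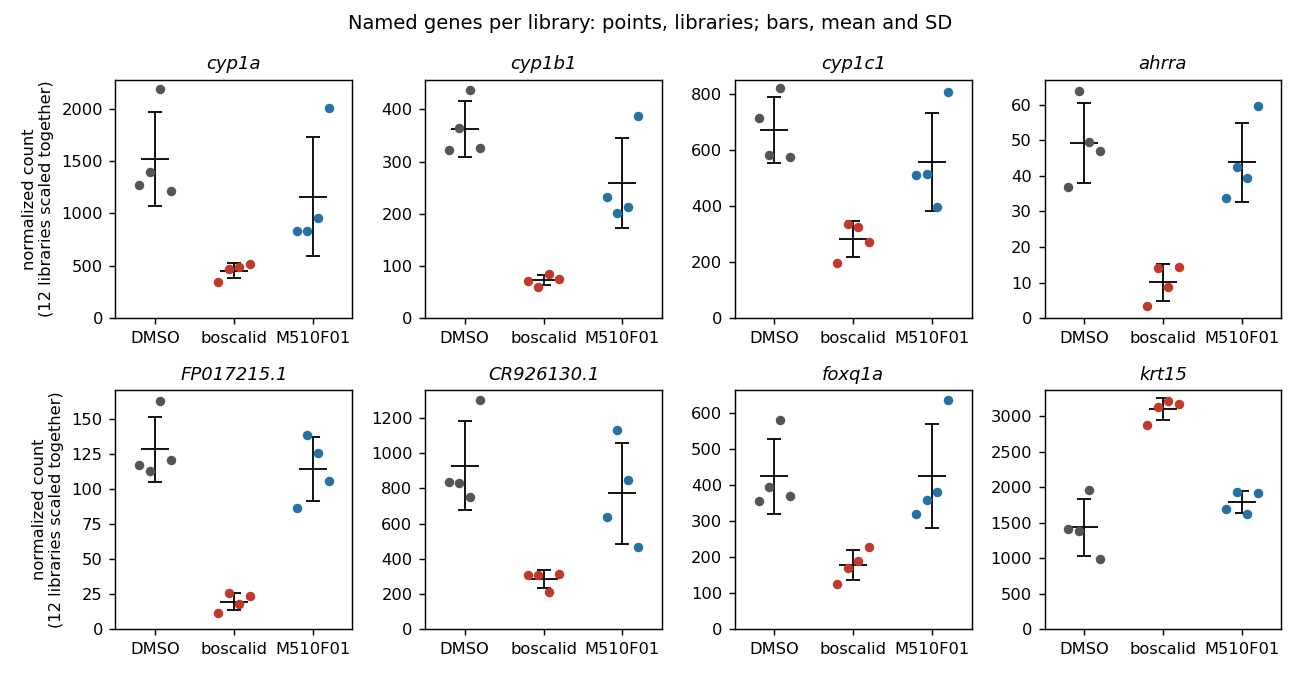
Normalized counts (vertical axes, starting at 0) of 8 genes in the 12 libraries scaled together, by group. Each point is a library, and the bars are the mean and SD of 4 libraries. For cyp1b1 the boscalid libraries lay between 60.3 and 85.6 and the DMSO libraries between 321.7 and 437.9.

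The AhR list as a whole was lower with boscalid (camera adjusted p = 2.8e-10, and adjusted p = 0.018 with an estimated correlation). Of its 14 measured members, 10 had a negative and 4 a positive fold change, and the median log2 fold change was -0.56. Over all genes tested 2 members fell, and 9 fell and 1 rose when adjusted over the list alone. Among those 9 were cyp1c1 (log2 fold change -1.26, SE 0.18, list-adjusted p = 0.00015), the forkhead factor foxq1a (-1.25, SE 0.20, list-adjusted p = 0.00030), the AhR repressor ahrra (-2.31, SE 0.39, list-adjusted p = 0.00030) and the receptor gene ahr2 itself (-0.52, SE 0.11, list-adjusted p = 0.0010). The member that rose was sox9b (0.61, SE 0.17, list-adjusted p = 0.0075), a chondrogenic transcription factor. All 4 boscalid libraries lay outside the range of the DMSO libraries for each of these genes. With numbers 1 and 2 against 3 and 4 as a term, chosen after seeing the data, the adjusted p with an estimated correlation was 0.062. With the preset correlation the adjusted p was at most 2.0e-07 in the 8 fits without 1 library; the estimated correlation was not run in those fits.

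**Figure D2:**
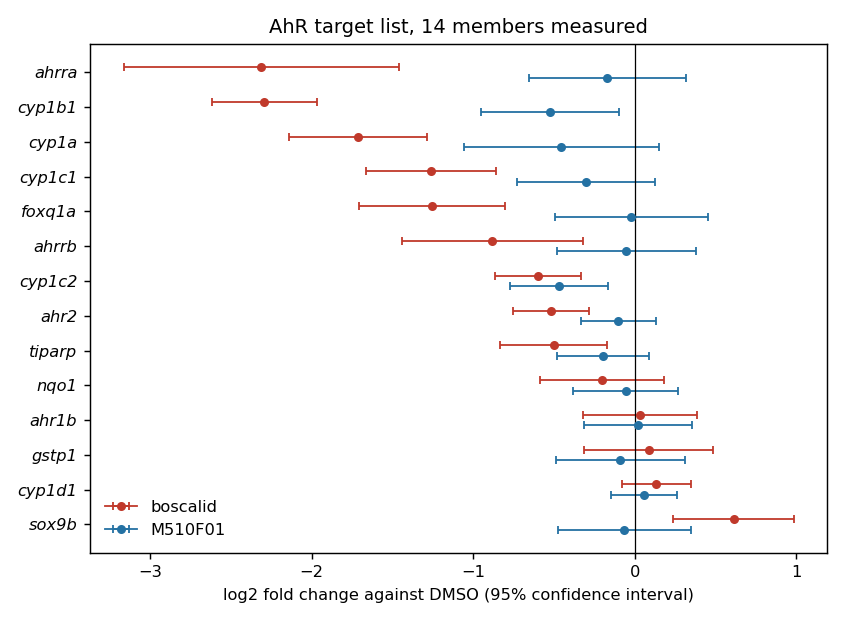
Log2 fold changes against DMSO of the 14 measured members of the AhR list, for boscalid and for M510F01. Points are estimates from 4 against 4 libraries and bars are 95% confidence intervals. The boscalid estimates run from -2.31 for ahrra to 0.61 for sox9b.

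The other genes named by rank did not pass the threshold over all genes, and their values are given without a call. Pkhd1l1, which encodes a large membrane protein, was at 2550 ± 459 with boscalid and 4923 ± 465 with DMSO (log2 fold change -0.96, SE 0.15, limma adjusted p = 0.12). The lipid transporter abca12 was at -0.69 (SE 0.13, adjusted p = 0.36) and the calpain protease capn3b at -0.60 (SE 0.12, adjusted p = 0.36). The keratin gene krt15 stood at 3076 ± 150 with boscalid and 1424 ± 399 with DMSO (1.15, SE 0.18, adjusted p = 0.12). The dicarboxylate transporter slc13a3 was at 0.73 (SE 0.13, adjusted p = 0.25). Cyp3a65, a xenobiotic-metabolizing enzyme of gut and liver, was at 0.28 (95% interval -0.32 to 0.88, adjusted p = 0.74).

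Boscalid's target enzyme showed no call. The 9 measured genes of complex II and its assembly factors had a median log2 fold change of 0.23, 7 of them positive, and the list did not pass the test (camera adjusted p = 0.12, and adjusted p = 0.58 with an estimated correlation). The median was 0.11 without DMSO replicate 1 and 0.31 without boscalid replicate 1. None passed over all genes or when adjusted over the list alone. The estimates for boscalid were -0.07 for sdha (95% interval -0.37 to 0.22), 0.23 for sdhb (-0.06 to 0.52), 0.23 for sdhc (-0.12 to 0.59), 0.55 for sdhda (0.01 to 1.08) and 0.28 for sdhdb (-0.03 to 0.59). Sdhda lay near the filter limit of 10, at 15.1 ± 0.82 normalized counts with boscalid and 10.1 ± 1.94 with DMSO.

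Transcripts of other parts of the respiratory chain and of the ribosome were higher with boscalid as lists under a preset correlation, by small amounts. All 38 complex I members had positive fold changes (median 0.28, camera adjusted p = 2.4e-10), as had the 18 members of ATP synthase (median 0.28, adjusted p = 2.2e-07) and the 71 ribosomal protein genes (median 0.21, adjusted p = 1.3e-08). With an estimated correlation the adjusted p was 0.58 for each, and the estimated correlations were 0.89, 0.88 and 0.95. No member passed over all genes or when adjusted over the list alone. Ndufb6 was at 0.43 (SE 0.15), ndufb3 at 0.41 (SE 0.15), atp5f1d at 0.38 (SE 0.15), atp5mc1 at 0.36 (SE 0.15), rplp1 at 0.26 (SE 0.17) and rpl24 at 0.27 (SE 0.19). Their loadings on the component that parted libraries of one group were 0.80 for ribosomal proteins, 0.65 for complex I and 0.59 for ATP synthase. With 1 library left out the medians ran from 0.18 (without DMSO replicate 1) to 0.41 (without DMSO replicate 3) for complex I, from 0.18 to 0.42 for ATP synthase in the same fits, and from 0.091 (without DMSO replicate 1) to 0.36 (without boscalid replicate 1) for ribosomal proteins.

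Photoreceptor and digestive enzyme transcripts followed the same direction. In the rod phototransduction list 22 of 25 members were positive (median 0.37, camera adjusted p = 2.8e-10, and adjusted p = 0.58 with an estimated correlation), and 10 rose when adjusted over the list alone, against 0 over all genes. They included the rhodopsin kinase gene grk1a (0.68, SE 0.13), the rod transducin subunits gnat1 (0.47, SE 0.12) and gngt1 (0.53, SE 0.14), and pde6a (0.48, SE 0.14). The loading of this list on the within-group component was -0.096. In the exocrine pancreas list 24 of 26 members were positive (median 0.40, adjusted p = 1.5e-09, and adjusted p = 0.58 with an estimated correlation), with no member passing either adjustment. The elastases ela2 and ela3l were at 0.81 (SE 0.23) and 0.63 (SE 0.21). The loading of the pancreas list was 0.46, and its median was 0.62 without DMSO replicate 3. The visual cycle list (median 0.30, adjusted p = 5.8e-07) and the lens crystallins (median 0.16, adjusted p = 5.8e-07) were likewise called under the preset correlation, each with adjusted p = 0.58 with an estimated correlation. The median of the crystallins was 0.094 without boscalid replicate 3. Rbp3 was at 0.41 (SE 0.17), rgrb at 0.34 (SE 0.12), crygm2d6 at 0.28 (SE 0.12) and crygm2d9 at 0.49 (SE 0.23).

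Immune lists lay in the other direction. In the interferon list 19 of 21 members were negative (median -0.27, camera adjusted p = 3.1e-06, and adjusted p = 0.50 with an estimated correlation), and 2 fell when adjusted over the list alone, against 0 over all genes: stat1b, a transcription factor of interferon signalling (-2.61, SE 0.53), and dhx58, an RNA helicase (-1.02, SE 0.25). In the myeloid and inflammation list 29 of 34 were negative (median -0.37, adjusted p = 8.9e-06, and adjusted p = 0.58 with an estimated correlation). When adjusted over that list alone 2 fell and 1 rose, against 0 over all genes. Those that fell were the inducible nitric oxide synthase gene nos2a (-3.41, SE 0.60) and the prostaglandin synthase gene ptgs2b (-1.27, SE 0.33), and the chemokine gene ccl34b.1 rose (1.22, SE 0.32). Without DMSO replicate 4 the median of the myeloid list was -0.17.

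**Figure D3:**
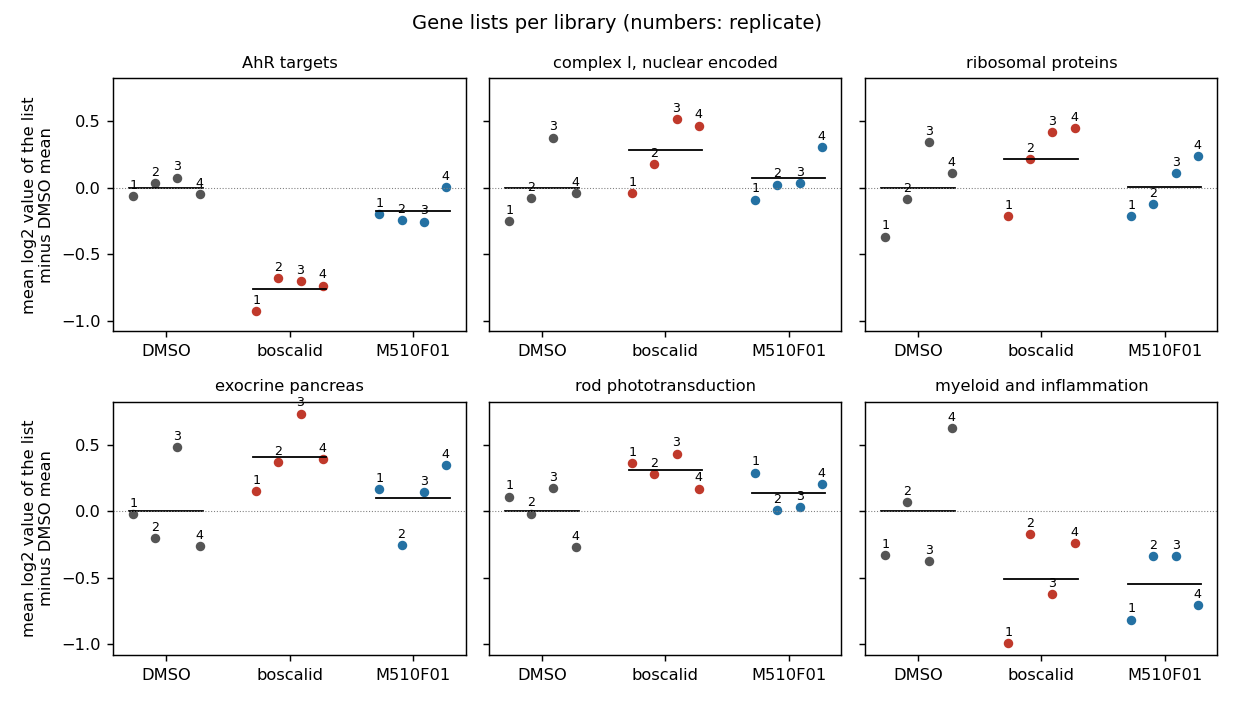
Mean log2 value of the members of 6 lists in each library, relative to the mean of the DMSO libraries (vertical axis), by group. Points carry the replicate number and lines are group means. In the AhR panel the boscalid libraries lie below every DMSO and M510F01 library, while in the complex I and ribosomal panels libraries of one group spread as widely as the groups differ.

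In all, 4 of 23085 genes tested passed an adjusted p of 0.05 with boscalid, all of them lower, and 1774 had an unadjusted p under 0.05 where 1154.2 would by chance. With 1 library left out the unadjusted count ran from 907 (without boscalid replicate 3) to 3819 (without boscalid replicate 1). EdgeR on the recovered reads also called 4 genes, and DESeq2 called 92 (22 higher and 70 lower). With numbers 1 and 2 against 3 and 4 as a term, chosen after seeing the data, limma called 19 (3 higher and 16 lower). The authors' deposited table lists 87 genes with an adjusted p under 0.05, 21 higher and 66 lower. Of these, 85 were tested here, and all 85 had the same sign. Both come from the same samples, so the shared sign is not independent support. In that table the log2 fold change was -2.31 for cyp1b1 and -1.74 for cyp1a. Of the 48 lists, 27 passed under the preset correlation and 1, the AhR list, with an estimated correlation. The count of genes ranged from 2 to 8 when 1 library was left out. Without DMSO replicate 1 or 2 or boscalid replicate 2 or 3 only 2 of the 4 genes kept their call, and cyp1b1 was 1 of them. FP017215.1 or CR926130.1 therefore lost its call in those fits, as did cyp1a. Cyp1a lost its call without DMSO replicate 1, 2 or 4 or boscalid replicate 2 or 3 (adjusted p from 0.054 to 0.11, and from 1.7e-12 to 0.11 over all its alternatives), with log2 fold changes of cyp1a between -1.80 and -1.52 in the fits without 1 library, while cyp1b1 kept it in each (adjusted p up to 0.0044).

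The second comparison set M510F01 against DMSO at the same concentration and age. No gene of 23193 tested passed the threshold (smallest limma adjusted p = 0.9998). An unadjusted p under 0.05 was found for 837 genes, where 1159.7 would by chance, and edgeR and DESeq2 on the recovered reads called 0 genes each. With 1 library left out the unadjusted count ran from 451 (without DMSO replicate 4) to 1877 (without DMSO replicate 3). The authors' deposited table has 0 genes with an adjusted p under 0.05 (smallest 0.514). The AP-1 factor genes fosab and fosl1a had log2 fold changes of -0.78 (SE 0.20) and -1.70 (SE 0.45), and casp6, a caspase, of -0.52 (SE 0.14). The finTRIM gene ftr63 was at -0.73 (SE 0.19), hhla2a.2 at -0.90 (SE 0.23) and znf1164 at -0.46 (SE 0.12). On the other side were gpr39, a zinc-sensing receptor (0.68, SE 0.17), dgat1a, an enzyme of triacylglycerol synthesis (0.48, SE 0.13), rab3b (0.41, SE 0.11) and pi4k2b (0.41, SE 0.11). These 10 genes had the smallest p among genes with a symbol and a mean count of at least 50, and each had an adjusted p of 0.9998.

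In the AhR list with M510F01, the estimates were -0.53 for cyp1b1 (95% interval -0.95 to -0.10) and -0.45 for cyp1a (-1.06 to 0.15). They were -0.30 for cyp1c1 (-0.73 to 0.13), -0.47 for cyp1c2 (-0.78 to -0.16) and 0.06 for cyp1d1 (-0.15 to 0.26). Members that were lower with boscalid were at -0.17 for ahrra (-0.65 to 0.32) and -0.02 for foxq1a (-0.50 to 0.45). Ahrrb was at -0.05 (-0.48 to 0.38), ahr2 at -0.10 (-0.34 to 0.13) and tiparp at -0.20 (-0.48 to 0.08). Sox9b, higher with boscalid, was at -0.06 (-0.48 to 0.35). The estimate for cyp1a was -0.75 without M510F01 replicate 4 and -0.26 without DMSO replicate 3. The list was called lower under the preset correlation (median -0.096, 12 of 14 members negative, camera adjusted p = 0.0054) and not with an estimated one (adjusted p = 0.69 with an estimated correlation), and its median was -0.22 without M510F01 replicate 4. No member passed over all genes or when adjusted over the list alone. For the target enzyme of the parent compound, sdha was at 0.03 (-0.29 to 0.36), sdhb at -0.02 (-0.28 to 0.24), sdhc at -0.02 (-0.39 to 0.35), sdhda at 0.20 (-0.46 to 0.86) and sdhdb at 0.00 (-0.28 to 0.28). Cyp3a65 was at 0.34 (-0.18 to 0.87).

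With M510F01 19 of the 48 lists passed under the preset correlation and 0 with an estimated correlation. The first was the myeloid and inflammation list, with 29 of 34 members negative (median -0.35, camera adjusted p = 1.0e-11, and adjusted p = 0.88 with an estimated correlation). When adjusted over the list alone 4 members fell, against 0 over all genes: fosl1a, ptgs2b (-0.94, SE 0.27), socs3b (-0.86, SE 0.24) and socs3a (-0.63, SE 0.18), the latter pair being inhibitors of cytokine signalling. Without DMSO replicate 4 the median of this list was -0.17. In the heat shock and unfolded protein list 31 of 36 members were negative (median -0.19, adjusted p = 4.6e-08, and adjusted p = 0.88 with an estimated correlation), among them trib3 (-0.51, SE 0.14) and hsp90b1 (-0.38, SE 0.15). Without DMSO replicate 4 its median was -0.13. In the intestine list 28 of 34 were positive (median 0.27, adjusted p = 9.1e-07, and adjusted p = 0.88 with an estimated correlation), among them the peptide transporter slc15a1b (0.49, SE 0.17) and chia.1 (0.41, SE 0.18), and its median was 0.43 without DMSO replicate 3. No member of the heat shock or intestine lists passed either adjustment. With boscalid, against the same DMSO libraries, the median was -0.12 for the heat shock list and 0.28 for the intestine list. Their camera adjusted p with boscalid was 0.019 and 7.4e-05, and 0.61 and 0.58 with an estimated correlation. The count of lists with M510F01 ranged from 11 (without DMSO replicate 4) to 26 (without DMSO replicate 3) when 1 library was left out.

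The third comparison tested parent and metabolite directly, M510F01 minus boscalid, at one concentration and age. Of 23131 genes tested 3 passed, all of them lower with boscalid. FP017215.1 differed by 2.53 on the log2 scale (SE 0.23, 95% interval 2.02 to 3.03, limma adjusted p = 0.0011), cyp1b1 by 1.77 (SE 0.19, interval 1.36 to 2.18, adjusted p = 0.0032) and zgc:165423 by 1.25 (SE 0.17, interval 0.88 to 1.63, adjusted p = 0.044). zgc:165423 (LL0000038882), named after its values were seen, stood at 2654 ± 351 with M510F01 and 1139 ± 287 with boscalid. An unadjusted p under 0.05 was found for 1063 genes, where 1156.6 would by chance. With 1 library left out the unadjusted count ran from 628 (without boscalid replicate 3) to 3462 (without boscalid replicate 1). EdgeR called 2 genes and DESeq2 20 (19 of them higher with M510F01). zgc:165423 lost its call in 10 of the 12 fits without 1 library.

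The AhR list separated the compounds. It was higher with M510F01 than with boscalid (median difference 0.36, camera adjusted p = 2.0e-08, and adjusted p = 0.0056 with an estimated correlation), with 10 of 14 members higher. Over all genes 1 member was called, and when adjusted over the list alone 7 were higher and 1 was lower with M510F01. Cyp1a differed by 1.26 (interval 0.69 to 1.82, list-adjusted p = 0.0011), cyp1c1 by 0.96 (0.50 to 1.42, list-adjusted p = 0.0015), foxq1a by 1.23 (0.74 to 1.73, list-adjusted p = 0.00052), ahrra by 2.14 (list-adjusted p = 0.00022) and sox9b by -0.68 (list-adjusted p = 0.0049). Over all genes the adjusted p was 0.62 for cyp1a, 0.73 for cyp1c1 and 0.32 for foxq1a. Without M510F01 replicate 4 the difference was 0.96 for cyp1a and 1.56 for cyp1b1.

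Other genes named by rank did not pass between the compounds. Pkhd1l1 differed by 0.92 (SE 0.14, limma adjusted p = 0.10), fgf7, a fibroblast growth factor gene, by 0.93 (SE 0.19), mamdc2b by 0.96 (SE 0.20), bco1l by 0.55 (SE 0.12), plin6, a perilipin gene, by 0.91 (SE 0.21) and krt15 by -0.79 (SE 0.16). In the epidermis and ionocyte list 6 members were lower with M510F01 when adjusted over the list alone, against 0 over all genes. Next to krt15 they included anxa1c (-0.81, SE 0.20), ca15a (-0.66, SE 0.17) and cyt1l (-0.97, SE 0.27). That list passed under the preset correlation (adjusted p = 0.0020) and had adjusted p = 0.73 with an estimated correlation; its loading on the within-group component was 0.62. Its median of -0.084 became 0.0086 without M510F01 replicate 1 and -0.21 without boscalid replicate 1. The difference was 0.11 for sdha (interval -0.21 to 0.43), -0.25 for sdhb (-0.52 to 0.02), -0.25 for sdhc (-0.62 to 0.11), -0.35 for sdhda (-0.90 to 0.21), -0.28 for sdhdb (-0.56 to 0.01) and 0.06 for cyp3a65 (-0.46 to 0.58). Of the 48 lists 21 passed under the preset correlation, led by ribosomal proteins and complex I, lower with M510F01 (medians -0.22 and -0.22), with adjusted p = 0.69 and adjusted p = 0.64 with an estimated correlation. The ribosomal median ran from -0.35 (without boscalid replicate 1) to -0.14 (without boscalid replicate 4). For genes not past the threshold, such a p does not show that the compounds act alike. The AhR list was the 1 list that also passed with an estimated correlation. When the exposed libraries were regrouped into sets of 4 and 4, 2 of 35 splits, the real one included, gave as many lists in that setting.

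Fold changes of both compounds against DMSO correlated across genes (Pearson 0.55, Spearman 0.51, 23131 genes, which are not independent replicates), with 68.3% of genes of the same sign. The Pearson correlation was 0.339 without M510F01 replicate 4. Both compounds share the DMSO libraries. Unchanged groups simulated against the same controls gave a mean correlation of 0.50 with independent genes, and 0.45 (central 95% from -0.34 to 0.90) when the covariance between genes was retained. The covariance was 0.0335, beside 0.0255 with independent genes and 0.0235 (central 95% from -0.0118 to 0.0843) when the covariance between genes was retained. With the DMSO libraries split 2 and 2 the correlation averaged 0.12 and ran from -0.092 to 0.245. The joint limma fit called 1 gene higher and 8 lower with boscalid and 0 with M510F01 (840 genes at an unadjusted p under 0.05, and 0 called by edgeR and by DESeq2 in its own table), so an overlap of called genes could not arise. At an unadjusted p under 0.05, 1083 genes were higher with boscalid and 389 with M510F01, and 167 were shared against an n1 × n2 / N of 18.2; 1067 and 451 were lower, and 146 were shared against 20.8. That expectation takes the comparisons as independent, which the shared DMSO libraries prevent.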

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

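Among the tests of the AhR genes, the respiratory and ribosomal lists and the myeloid list, those chosen after the result was seen are those of a single library and of organ lists for the AhR genes, that of the replicate numbers, and the term for numbers 1 and 2 against 3 and 4. Among 147 groups of 4 values tested, 15 had a value far from the other 3, where chance gives about 1 in 20 groups, or 7.3; 9 of these groups were DMSO, 2 boscalid and 4 M510F01. M510F01 replicate 4 was highest of its group for cyp1b1 (386.38 normalized counts, others 201.7 to 233), cyp1a (2005.16, others 829.2 to 959) and capn3b (292.99). DMSO replicate 4 was lowest for grk1a (287.1) and highest for capn3b (295.64), CR926130.1 (1303.17) and casp6 (424.79). DMSO replicate 3 was highest for FP017215.1 (163.1), dgat1a (209.56) and nqo1 (844.18). DMSO replicate 2 was highest for plin6 (176.09) and DMSO replicate 1 for pi4k2b (223.41). Boscalid replicate 3 was lowest for CR926130.1 (210.86) and highest for wfikkn1 (0.86, others 0), and M510F01 replicate 1 was lowest for rab3b (541.73). Between M510F01 and boscalid the test of the difference itself passed for FP017215.1 (2.5271 on the log2 scale), cyp1b1 (1.7691), zgc:165423 (1.2511) and the AhR list (median 0.3602).

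The AhR list was lower with boscalid in all 4 libraries. Of the 35 splits of the 8 libraries, the real one gave the smallest camera p for this list, 1.7e-11 with the preset correlation. The smallest p of the others was 9.6e-06. First place among 35 splits does not by itself exclude chance, and this comparison made no allowance for choosing this list among those tested. With an estimated correlation a list passed in 1 of the 35 splits, the real one, and in 0 of the others. The list median was at most -0.5484 under TMM and upper-quartile rescaling, so the choice among these scalings matters little. These put the median of all genes at 0.0034 and 0.0108 only, so a larger error of scaling was not tested. The values argue against a single library as the source, with a list median of at most -0.5273 whichever was left out. Fewer cells of organs that express these genes would lower other genes of those organs too, but the lowest lower quartile of the liver, intestine, vasculature, epidermis and kidney lists was -0.1557. These values speak only to a loss of those organs as a whole. Fewer cells at other sites, or of a small group of cells within these organs, were not tested. A response of AhR target genes to boscalid is therefore a hypothesis that may account for the pattern. The call of the list with an estimated correlation ended with a term for numbers 1 and 2 against 3 and 4, where the adjusted p was 0.062. That term is balanced over the groups, so it cannot change the folds. Differences of clutch or tank that follow the groups were not tested.

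Respiratory chain, ribosomal and pancreas lists were higher with boscalid, and most of them also vary between libraries of one group. The first within-group component parted numbers 1 and 2 from 3 and 4 in each group (exact two-sided permutation p = 0.00926, the smallest that regroupings within groups allow). This grouping was chosen because the component showed it, so the p only describes it, and whether the numbers mark a shared order of collection or preparation stays open. Across genes, which are not independent replicates, the boscalid fold correlated with the loading on this component at r = 0.363 and the M510F01 fold at r = -0.016. Across the 48 lists r was 0.168 for the boscalid fold (95% interval -0.122 to 0.432), and lists are not independent. A bound of 0.3 had been set before the result, and the interval was required to lie below it only after the result was seen; as it does not, this axis and an effect of boscalid cannot be told apart for these lists. Chance was not excluded for the count of 27 lists (2 of 35 splits gave as many, highest other 27).

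The myeloid and inflammation list was lower with both compounds, which share the DMSO libraries. Without DMSO replicate 4 its median was -0.1719 with boscalid and -0.1743 with M510F01, against -0.37 and -0.35 with all libraries. These values just miss the bound set for the shared controls as the cause, and do not meet the bound set against it. High values in 1 DMSO library and a response to both compounds therefore cannot be told apart. Chance was not excluded for the 19 lists with M510F01 (18 of 35 splits gave as many, highest other 26).

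For the counts of genes with boscalid and between the compounds chance was not excluded. With boscalid 2 of 35 splits gave at least the real 4 genes, and the highest other gave 3166, which parted DMSO replicates 1, 2 and 4 and boscalid replicate 1 from the rest. With M510F01 the splits test nothing, since 35 of 35 must give at least the real 0 (limma; 837 at an unadjusted p under 0.05, and 0 by edgeR and by DESeq2), and the highest other, 2246, parted numbers 1 and 2 from 3 and 4. Between M510F01 and boscalid 2 of 35 gave at least the real 3, with 1199 the highest other. For lists 7 of 35 gave at least the real 21, with 24 the highest other. With an estimated correlation 2 of 35 gave at least the real 1 list, with 1 the highest other, so chance was not excluded for that count either. Splits that call so many genes point to a structure of the samples that the groups do not explain.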

How the results depend on the processing

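Of the alternatives, those with the first component as a covariate, with libraries that stand apart left out and with numbers 1 and 2 against 3 and 4 as a term were chosen after seeing the data. With boscalid the count of genes stayed at 4 or 5 with other pseudocounts, filters, rescalings, limma without the robust setting and edgeR, and each of these called all 4 genes. It was 22 with array quality weights, 92 with DESeq2, 90 (31 higher and 59 lower) with the replicate block, 9 in the joint fit, 765 with the first component as a covariate, 19 with the term for numbers and 1 without DMSO replicate 3 and boscalid replicates 3 and 4. The cause was not tested, except that fewer libraries were used in the last. With the component as a covariate 7 of 35 splits gave as many genes, so that count is not calibrated. For M510F01 the count was 1 with the replicate block and 0 otherwise. Between the compounds it was 8 with array quality weights, 20 with DESeq2, 8 with the replicate block, 682 with the first component, 5 with the term for numbers and 2 to 4 otherwise; the cause was not tested. Same-number libraries were to count as pairs if all their correlations were over 0.1; 4 of 12 were not (range -0.0243 to 0.51), and 5 of 12 were best with their own number, so the numbers were not taken as pairs. Libraries numbered 1 did deviate together (0.482 to 0.51), so a part of the numbering may be shared, as the 19 genes with the term for numbers leave open.

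Lists past the threshold numbered 27, 19 and 21 with a preset correlation for boscalid, M510F01 and the direct comparison. They were 1, 0 and 1 with an estimated correlation, 1, 0 and 1 with fry, and 0, 0 and 1 with an estimated correlation and the term for numbers; the cause was not tested. With 1 library left out, genes ranged from 2 to 8, 0 to 0 and 2 to 3, and lists from 21 to 28, 11 to 26 and 16 to 25. For boscalid 2 genes passed without DMSO replicate 1 or 2 or boscalid replicate 2 or 3, and 8 without DMSO replicate 3; for M510F01 11 lists passed without DMSO replicate 4. The correlation of fold changes of the 2 compounds, 0.553, was 0.116 as the mean of DMSO splits and ranged from 0.339 (without M510F01 replicate 4) to 0.705 (without DMSO replicate 3). No call reversed. At this depth and spread the simulated data left most 1.5-fold changes uncalled.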

Other observations

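Several gene groups were called with a preset correlation only. In the glycolysis list 29 of 32 members were positive with boscalid (median 0.15, from 0.095 without DMSO replicate 1 to 0.23 without DMSO replicate 3; camera adjusted p = 1.2e-05, and adjusted p = 0.58 with an estimated correlation), and pfkmb, a phosphofructokinase gene, rose when adjusted over the list alone (0.83, SE 0.18), against 0 members over all genes. Cone phototransduction genes had a median of 0.28 with boscalid, from 0.17 without DMSO replicate 4 to 0.41 without DMSO replicate 3 (adjusted p = 1.2e-05, and adjusted p = 0.58 with an estimated correlation), with the cone opsin genes opn1sw1 at 0.49 (SE 0.19) and opn1sw2 at 0.46 (SE 0.19). Erythroid and haem genes lay lower with M510F01, 18 of 20 negative, with the globin gene hbbe1.1 at -0.42 (SE 0.12). Their median was -0.18, from -0.29 without DMSO replicate 3 to -0.075 without M510F01 replicate 3 (camera adjusted p = 0.00050, and adjusted p = 0.88 with an estimated correlation). With boscalid, against the same DMSO libraries, 15 of 20 were negative (median -0.14, camera adjusted p = 0.024, and adjusted p = 0.58 with an estimated correlation). In cardiac muscle genes actc1a was lower with M510F01 than with boscalid when adjusted over the list alone (-0.41, SE 0.10, limma list-adjusted p = 0.026). The camera adjusted p of the cardiac list as a whole was 0.00071, and adjusted p = 0.58 with an estimated correlation.

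The test of genes beside the cyp1 genes was chosen, the bound against it reworded and the sign of r required after the result was seen; that of sox9b was set before. A hypothesis was that sox9b and its neighbour FP017215.1 vary inversely also without boscalid, which might link their opposite changes. Over the 8 libraries without boscalid, as deviations from group means, Pearson's r was -0.466 (exact permutation p = 0.293) and Spearman's rho -0.50 (exact permutation p = 0.262), and r was -0.528 without DMSO replicate 3 and M510F01 replicate 2, so the relation stays open. A further hypothesis was that genes that differ with boscalid, FP017215.1, CR926130.1, pkhd1l1, zgc:165423 and foxq1a (lower) and krt15 (higher), vary with the mean of cyp1a, cyp1b1 and cyp1c1 in the same 8 libraries, which needs a positive r for the lower genes and a negative r for krt15. For 4 of the 6 genes r had the opposite sign, and the smallest adjusted exact permutation p was 0.108. The relation of foxq1a (r = 0.944) rests on M510F01 replicate 4 and DMSO replicate 3, without which r was -0.0641. Against the hypothesis stood CR926130.1 (r = -0.786, exact permutation p = 0.0503, adjusted 0.108; rho -0.857, exact permutation p = 0.0139; r -0.71 without the same libraries), pkhd1l1 (r = -0.474, exact permutation p = 0.337, adjusted 0.506; rho -0.81, exact permutation p = 0.0278) and krt15 (r = 0.572, exact permutation p = 0.0417, adjusted 0.108), though r of krt15 was 0.226 without the same libraries. FP017215.1 went from r = 0.107 to -0.636 without them. No adjusted p passed, so the values neither bear the hypothesis out nor exclude it.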
